A study of Mus musculus with 8 samples.

How the data were processed

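RNA sequencing libraries were made from mouse hematopoietic stem and progenitor cells that had been expanded in culture. The cells carried 2 floxed Elp1 alleles and a tamoxifen-inducible Cre recombinase (UBC-cre/ERT2), per the labels. They had been pretreated with 4-hydroxytamoxifen or vehicle, were then cocultured with primary glia to start myeloid differentiation, and were harvested after 48 h as sorted CD45-positive cells. There were 4 vehicle and 4 4-hydroxytamoxifen libraries, and the titles numbered the replicates 1 to 4 in each group. The labels do not say whether the replicates were separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical. All libraries were labelled female, and the Y-linked list had 0 reads in all 8. No library combined 4-hydroxytamoxifen with intact Elp1 alleles or with cells lacking Cre.

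The deposited files held whole-number read counts per gene, 1 file per library. Per the submitters' processing notes, STAR 2.7.10a, SAMtools 1.16.1 and HTSeq 0.11.2 were used with the mouse build GRCm39 (mm39). The annotation release, the counting mode and the strand setting were not given in the sources used here, so reads of overlapping, antisense or near-identical genes could not be assigned with certainty. Each file listed 56832 genes and 5 entries that name no gene. Those entries held 9.89% to 12.3% of the reads and were left out of library sizes and tests. Total gene counts per library ranged from 18150354 to 27478761, and 15084 to 18175 genes had at least 1 read. Over the 12 pairs of libraries of the same group, the lowest chi-square per degree of freedom was 11.1, so no pair agreed within sampling noise. Values were 11.1 to 48.9 for pairs within libraries 1 and 2 or 3 and 4, and 45.8 to 237 across these sets. Each library was counted as 1 replicate, which these values do not show to be independent.

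The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM factors, robust dispersion estimates and the group as the only term. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12855 genes. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Log2 fold changes are 4-hydroxytamoxifen over vehicle, with a standard error taken as the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to a common library total with TMM factors, given as mean ± SD over 4 libraries. Summed CPM of gene lists used the plain library totals. For Elp1 an exact two-sided permutation test over the 70 splits of the 8 CPM values was added.

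Before the data were examined, 27 gene lists, the rule for named genes, the main design and the first set of alternative settings were written down. Of 686 list entries, 684 were found in the counts, 7 of them under another name taken from the RefSeq gene table of GRCm38.p6. Lists with at least 3 tested genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with camera at a correlation estimated for each list, and with fry. Camera compares a list with the other genes, and fry asks whether the genes of a list move, on balance, one way. The Y-linked list had no tested gene, which left 26 lists. Named genes were the Elongator subunits, then up to 12 rises and 12 falls with the largest change among genes past the threshold with a mean of at least 4 CPM and no overlap between the groups, leaving out predicted models. For each list, up to 4 members past the threshold with the smallest adjusted p were named, or otherwise the 2 most abundant. The same rule was also applied to the blocked fit, a choice made after its values were seen, with the same direction in all 4 pairs in place of no overlap.

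Whether the replicate numbers pair the libraries was checked on the deviations of log2 CPM (prior count of 2) from the group means. The correlations between the vehicle and the 4-hydroxytamoxifen library of one number were 0.403, 0.491, 0.493 and 0.448, all above the preset minimum of 0.1. The numbers were therefore treated as pairs by that rule. Libraries of different numbers within a set correlated as well, vehicle 1 with 4-hydroxytamoxifen 2 at 0.661 and vehicle 4 with 4-hydroxytamoxifen 3 at 0.487. The data thus show the split into libraries 1 and 2 and libraries 3 and 4, and neither they nor the labels show that each number marks a pair. With this limit, the values of a fit with the replicate number as a block are given where they change a call or a count. Alternative settings chosen in advance were RLE factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 4 libraries, no robust estimation, the block, and each library left out in turn. Alternatives added after seeing the data were a term for libraries 1 and 2 against 3 and 4, each of these sets alone, 4-hydroxytamoxifen 1 and 3 left out, the ribosomal RNA gene Rn18s-rs5 removed, lists without members shared with the ATF4 list, and the blocked fit with other tools and filters and without each pair.

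The tests were run on simulated negative binomial counts made from the fitted means, library sizes and dispersions, with 200 single genes changed by known folds. Without the block, edgeR tested 12571 genes and recovered 1 of 50 genes changed 1.5-fold, 22 of 50 changed 2-fold and 49 of 50 changed 4-fold, and 3.94% of its calls were false. On the same counts 20.6% of the DESeq2 calls were false. With the block, edgeR tested 12553 genes and recovered 27 of 50, 45 of 50 and 49 of 50, and 5.45% of its calls were false. The counts of each simulation were made from the fit it tested. Pairs were thus true by construction with the block, and the group means used without it held no split of the libraries into sets. The shares of false calls therefore do not measure those in the real libraries, whose pairing is not shown. In both simulations a changed list was called and 0 of 20 unchanged lists were called with the preset correlation. The simulated genes varied independently of each other, so this does not test that correlation on lists whose genes move together. Without the block, correlations estimated for the real lists ranged from -0.109 (erythroid) to 0.911 (mitochondrially encoded genes), with 0.349 for ATF4 targets. GC content, transcript length and codon content came from GENCODE M21, an annotation of GRCm38, matched by gene symbol. No coordinates were used, since that build differs from the one behind the counts.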

Results

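Expression was profiled in CD45-positive hematopoietic cells in early myeloid differentiation, after 48 h of coculture with primary glia. Elp1 encodes the scaffold subunit of Elongator, the complex that modifies wobble uridines of transfer RNAs. In these cells 4-hydroxytamoxifen activates Cre, which recombines the floxed Elp1 alleles. The design compared 4 libraries from cells pretreated with 4-hydroxytamoxifen with 4 from cells pretreated with vehicle, and asked how gene expression differs with Elp1 deficiency. Library totals were 23729000 ± 2599670 gene counts (SD, n = 4) with vehicle and 21477000 ± 2534640 with 4-hydroxytamoxifen.

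The libraries differed more by replicate set than by treatment. The first principal component held 52.3% of the variance and separated libraries 1 and 2 from libraries 3 and 4 in both groups. Values within each of these sets are therefore given for Elp1 and for each list past the threshold. The 4-hydroxytamoxifen libraries 1 and 3 also held more 18S ribosomal RNA reads (Rn18s-rs5), at 0.874% and 2.23% of gene counts, against 0.0963% to 0.513% in the other 6.

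**Figure D1:**
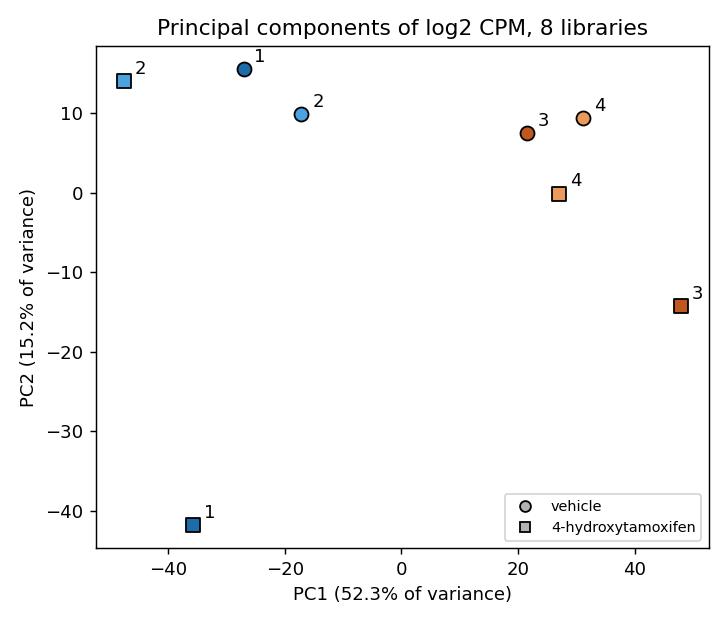
Principal components of log2 CPM for the 8 libraries, with the first component (52.3% of variance) on the x axis and the second (15.2%) on the y axis. Circles are vehicle and squares 4-hydroxytamoxifen libraries, numbered by replicate. Libraries 1 and 2 lie on the negative side of the first component and libraries 3 and 4 on the positive side.

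Elp1 transcripts fell after 4-hydroxytamoxifen in all 4 pairs of libraries. Elp1 was at 63.9 ± 5.77 CPM with vehicle and 29.9 ± 4.91 CPM with 4-hydroxytamoxifen (SD, n = 4), which is 46.8% of the vehicle level and 40.2% to 52.9% within single pairs. The log2 fold change was -1.09 with a standard error of 0.156 (edgeR adjusted p = 0.0469), and the 4 libraries of each group did not overlap (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). With the replicate number as a block it was -1.10 (adjusted p = 8.10e-05), and it was -1.19 within libraries 1 and 2 and -1.01 within libraries 3 and 4. The counts cover the whole gene and the labels do not say which exons are floxed, so the remaining reads do not measure how many cells kept an intact allele. The unblocked call was lost when any single library other than 4-hydroxytamoxifen 3 was left out (adjusted p = 0.0504 to 0.267).

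The other 5 Elongator subunits did not pass the test. Elp3, the catalytic subunit, had a log2 fold change of 0.10, Elp2 of 0.03, Elp4 of -0.02, Elp5 of 0.01 and Elp6 of -0.13. The Elongator list as a whole was lower in camera (adjusted p = 0.00665, and adjusted p = 0.310 with an estimated correlation), with Elp1 as the only member that fell, over all genes and adjusted over the list alone. The list did not pass without 4-hydroxytamoxifen 1 (adjusted p = 0.1), 4-hydroxytamoxifen 2 (0.157) or vehicle 4 (0.0796), by limma-voom (0.0685), by fry (0.445) or in libraries 3 and 4 alone (0.230). Its median log2 change was -0.01, and -0.10 within libraries 1 and 2 and -0.02 within libraries 3 and 4. The 10 tested partners of wobble uridine modification, among them Urm1 (-0.04) and Trmt112 (0.01), did not pass as a list (adjusted p = 0.852).

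**Figure D2:**
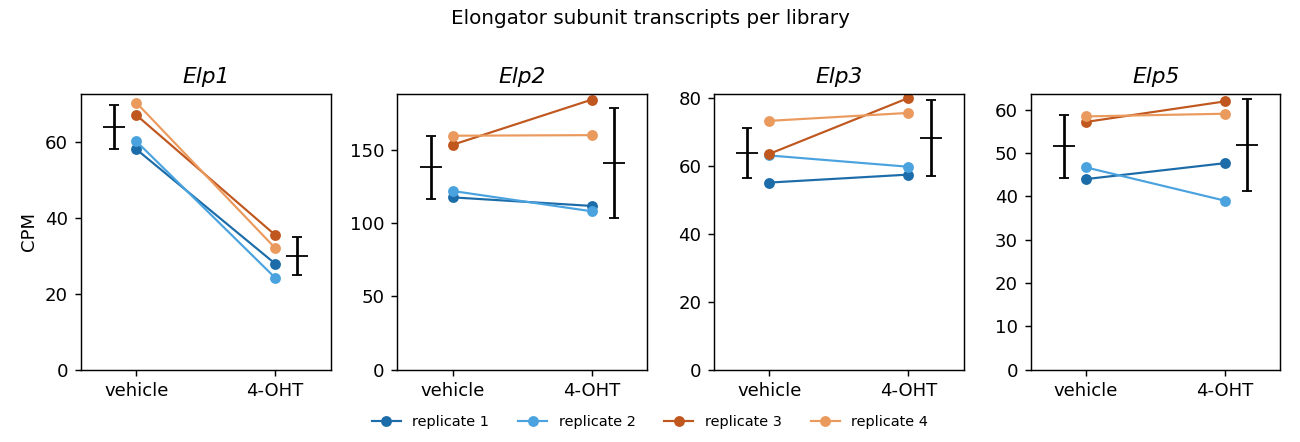
CPM of 4 Elongator subunit transcripts in each library, with vehicle on the left and 4-hydroxytamoxifen (4-OHT) on the right of each panel. Lines join libraries of one replicate number, and the bars beside them are the mean and SD of 4 libraries. Elp1 goes from 63.9 to 29.9 CPM, while Elp2, Elp3 and Elp5 overlap between the groups.

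Genes of the integrated stress response rose with 4-hydroxytamoxifen. ATF4 is the transcription factor that drives this response, which is set off by amino acid shortage and other stresses. Asns, which encodes asparagine synthetase, rose from 35.2 ± 8.71 to 126.0 ± 23.02 CPM, a 3.58-fold change. Chac1, a glutathione-degrading enzyme, rose 6.66-fold from 2.46 ± 0.591 CPM, and Trib3, a pseudokinase induced by ATF4, rose 8.33-fold from 3.20 ± 1.11 CPM. All 40 tested members of the ATF4 list had a log2 fold change above 0, with a median of 0.60.

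Of 12855 genes tested, 9 passed the threshold, 8 higher and 1 lower (Elp1), and all 9 changed at least 2-fold. The count was 0 without vehicle 1 (edgeR, 240 at an unadjusted p under 0.05, 16 by DESeq2, 0 by limma-voom), 0 without 4-hydroxytamoxifen 4 (288, 23 by DESeq2, 0 by limma-voom), 1 without vehicle 2 and 2 without vehicle 4, so the calls of the rises depend on single libraries as well. At an unadjusted p under 0.05 there were 307 genes. In 285 genes (2.22%) the groups did not overlap, and chance alone gives 2.86%. Of the 8 rises, 6 were on the ATF4 list. Besides Asns (log2 fold change 1.84 ± 0.208 SE, adjusted p = 0.0151), Chac1 (2.74 ± 0.264, adjusted p = 0.0145) and Trib3 (3.06 ± 0.365, adjusted p = 0.0198) these were Aldh1l2, Gpt2 and Cth. Aldh1l2, a mitochondrial folate enzyme, rose by 4.74 from only 11 reads over the 4 vehicle libraries to 275. Gpt2, the mitochondrial alanine aminotransferase, rose by 1.23 from 7.40 ± 0.459 to 17.4 ± 1.62 CPM. Cth, the enzyme that makes cysteine from cystathionine, rose by 3.92 from 14 to 195 reads and lies outside the rule for named genes, so it was chosen after its values were seen. The other 2 rises were Slc1a4, a neutral amino acid transporter (2.18 ± 0.266, adjusted p = 0.0199), and Cox6a2, a subunit of cytochrome c oxidase (1.98 ± 0.217, adjusted p = 0.0147).

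The ATF4 list rose as a whole (camera adjusted p = 2.08e-112, adjusted p = 0.0104 with an estimated correlation, fry adjusted p = 0.0250). Of its members 6 rose over all genes, and 25 adjusted over the list alone. With the block 18 rose over all genes, and 34 adjusted over the list alone (adjusted p = 0.0379 with an estimated correlation). Its median was 0.53 within libraries 1 and 2 and 0.68 within libraries 3 and 4. Summed over the list, expression was 3845 ± 492 CPM with vehicle and 5451 ± 894 CPM with 4-hydroxytamoxifen.

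With the replicate number as a block, 41 genes passed, 24 higher and 17 lower, among them all 9 above. Each of the 41 moved in the same direction in all 4 pairs and had the same sign within both sets of libraries. The fit chose these genes from the same 4 pairs, so this agreement is largely built in and is no separate support. Higher in this fit, and not past the threshold in the unblocked edgeR fit above, were the transcription factors Atf5 (1.58 ± 0.123 SE, adjusted p = 9.24e-07) and Ddit3 (1.05 ± 0.164, adjusted p = 0.00431), the branched-chain aminotransferase Bcat1 (1.47), the secreted glycoprotein Stc2 (1.48), the glycine transporter Slc6a9 (2.09) and the stress protein Nupr1 (0.98). Without the block the adjusted p of Atf5 was 0.0631 and that of Ddit3 was 0.0658, and all 6 of these genes passed by DESeq2 without the block and by edgeR within libraries 3 and 4 alone. These fits reuse the libraries that chose the 6 genes, so they are no separate support. DESeq2 without the block also made 20.6% false calls on simulated counts. Within libraries 1 and 2 alone only Atf5 (adjusted p = 0.00400) and Slc6a9 (0.0487) passed, and Ddit3 (0.3004), Bcat1 (0.126), Stc2 (0.438) and Nupr1 (0.755) did not. Chosen after their values were seen, Atf4 itself rose by 0.52 in the blocked fit (adjusted p = 0.0306), from 246 ± 38.7 to 352 ± 37.7 CPM. The folate enzyme Mthfd2 rose by 0.73, and the chains of a large amino acid transporter, Slc7a5 and Slc3a2, by 0.78 and 0.61. Atf4, Mthfd2, Slc7a5 and Slc3a2 did not pass by edgeR over the 8 libraries without the block.

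**Figure D3:**
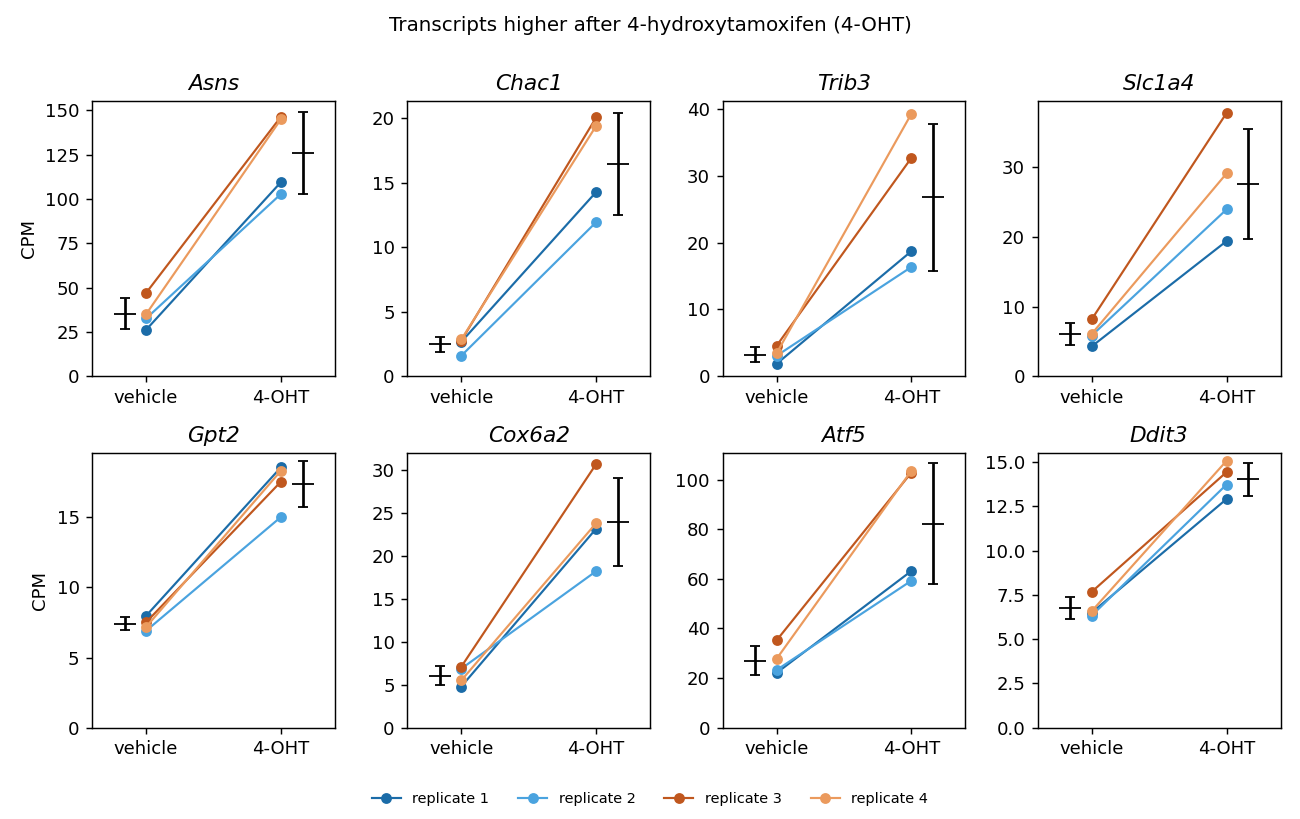
CPM of 8 transcripts in each library, with vehicle on the left and 4-hydroxytamoxifen (4-OHT) on the right of each panel. Lines join libraries of one replicate number, and the bars beside them are the mean and SD of 4 libraries. All 8 are higher with 4-hydroxytamoxifen in all 4 pairs. With the same low-count filter, Atf5 and Ddit3 passed by edgeR over the 8 libraries with the replicate block and not without it.

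Genes of neutrophil granules and granulocyte maturation were lower with 4-hydroxytamoxifen. All 20 tested members of the neutrophil list had a log2 fold change below 0, with a median of -0.83, and their summed expression was 7598 ± 1255 CPM with vehicle and 4972 ± 1012 CPM with 4-hydroxytamoxifen. Elane, which encodes neutrophil elastase, was at 858 ± 121 and 496 ± 128 CPM. Fcnb, a ficolin of granulocyte progenitors, was at 40.4 ± 17.9 and 12.96 ± 4.56 CPM, and Cebpe, a transcription factor of late granulocyte differentiation, at 27.1 ± 7.73 and 14.5 ± 3.06 CPM.

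As a list these genes fell (camera adjusted p = 5.59e-32, adjusted p = 0.0448 with an estimated correlation), but with the block the adjusted p with an estimated correlation was 0.0750. By edgeR without the block 0 members fell over all genes (12 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom), and 11 adjusted over the list alone. In the blocked fit 6 fell over all genes, and 9 adjusted over the list alone. Those named by the rule were Elane (-0.82 ± 0.114 SE, adjusted p = 0.00109), Fcnb (-1.59 ± 0.225, adjusted p = 0.00160), Cebpe (-0.88 ± 0.146, adjusted p = 0.00875) and Cd177 (-1.95 ± 0.373, adjusted p = 0.0270), and the other two were Prtn3 (-0.57) and Ms4a3 (-0.51), the latter chosen after its values were seen. Mpo, the most abundant granule transcript at 3899 ± 349 and 2848 ± 941 CPM, did not pass in either fit (blocked log2 fold change -0.51, adjusted p = 0.225). The list's median was -0.70 within libraries 1 and 2 and -0.95 within libraries 3 and 4.

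**Figure D4:**
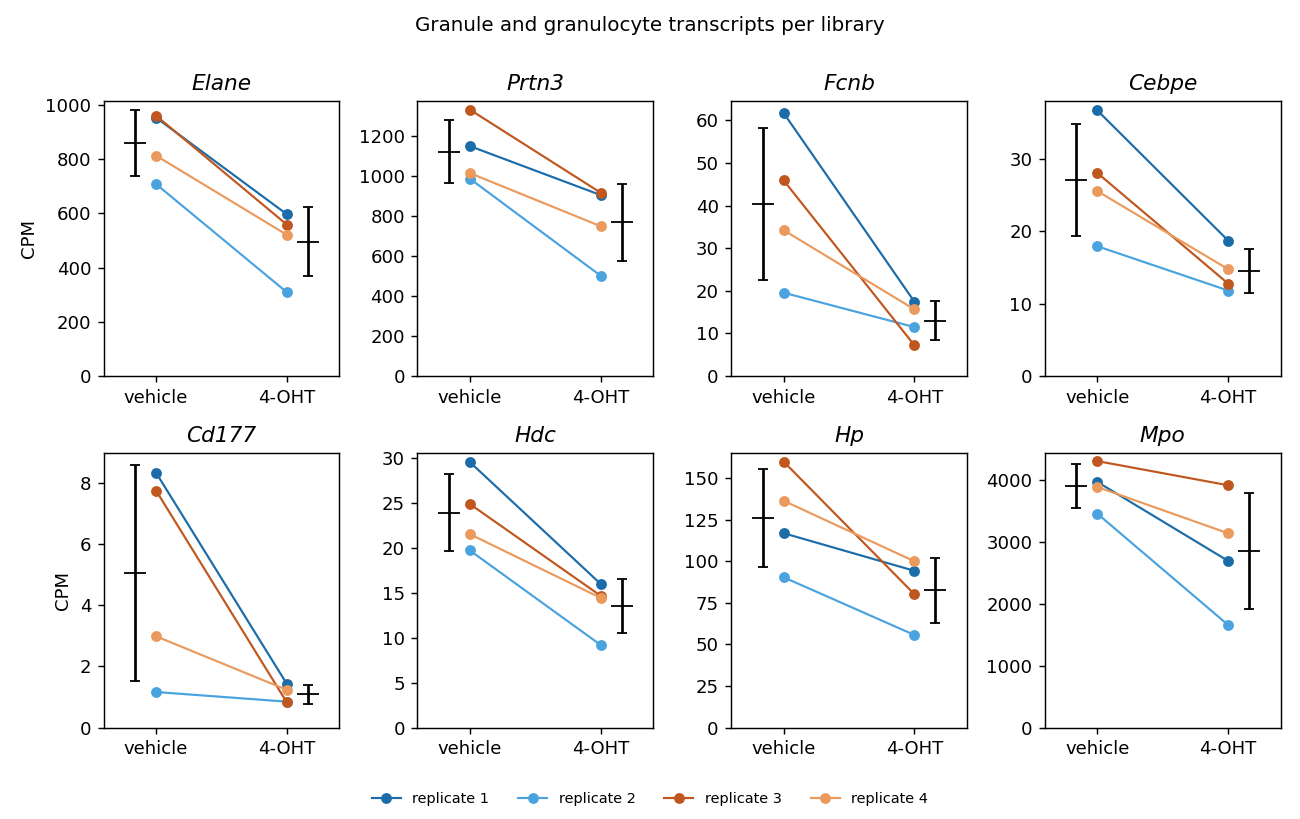
CPM of 8 granulocyte and mast cell transcripts in each library, with vehicle on the left and 4-hydroxytamoxifen (4-OHT) on the right of each panel. Lines join libraries of one replicate number, and the bars beside them are the mean and SD of 4 libraries. All 8 are lower with 4-hydroxytamoxifen in all 4 pairs; 7 passed the threshold in the blocked fit and Mpo did not.

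Mast cell, basophil and eosinophil genes fell as a list, with a median of -0.59 (camera adjusted p = 1.47e-09, adjusted p = 0.0360 with an estimated correlation, and 0.0668 with the block and an estimated correlation). Of the 10 tested members 0 fell over all genes by edgeR (4 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom) and 3 adjusted over the list alone. In the blocked fit 3 fell over all genes and 5 adjusted over the list alone. The 3 were Hdc, the histamine-forming enzyme (-0.83 ± 0.148 SE, adjusted p = 0.0149), Prg2, the eosinophil major basic protein (-1.70, adjusted p = 0.0122), and the tryptase Tpsb2 (-3.11 ± 0.422 SE, adjusted p = 0.00108). Tpsb2 had only 3 reads in vehicle 2 and 0 in 4-hydroxytamoxifen 2, and its values overlapped between the groups. Within libraries 1 and 2 its change was -2.49 ± 1.335 SE (edgeR adjusted p = 0.755). The list's median was -0.29 within libraries 1 and 2 and -0.46 within libraries 3 and 4. Other falls in the blocked fit were the serine protease Prss57 (-0.76), haptoglobin Hp (-0.61), complement C3 (-0.60), the antibacterial protein Pglyrp1 (-0.91) and the triglyceride synthesis enzymes Dgat2 (-0.85) and Mogat2 (-1.22).

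Monocyte and macrophage genes were lower as a list (median -0.13, camera adjusted p = 2.38e-06, adjusted p = 0.310 with an estimated correlation). Of 28 tested members 0 passed over all genes by edgeR (4 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom) and 0 adjusted over the list alone, and in the blocked fit 1 fell over all genes, the complement gene C1qa (-1.35 ± 0.260 SE, adjusted p = 0.0272), and 4 adjusted over the list alone. The list's adjusted p was 0.137 without 4-hydroxytamoxifen 3, and its medians were -0.03 within libraries 1 and 2 and -0.31 within libraries 3 and 4. Lyz2 and Csf1r, the most abundant members, had log2 fold changes of 0.06 and -0.10. Stem and progenitor genes were higher as a list (median 0.13, camera adjusted p = 0.00985, adjusted p = 0.544 with an estimated correlation), with 0 of 26 past the threshold by edgeR over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom). That list's adjusted p was 0.0982 to 0.205 when vehicle 3, vehicle 4 or any of 4-hydroxytamoxifen 1, 2 and 3 was left out, and its medians were 0.05 within libraries 1 and 2 and 0.22 within libraries 3 and 4. Cd34 was at 508 ± 33.0 and 560 ± 46.6 CPM (log2 fold change 0.14).

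Sterol synthesis genes fell as a list by a small amount. Their median was -0.19 with 22 of 23 members below 0 (camera adjusted p = 7.94e-08, adjusted p = 0.0407 with an estimated correlation). By fry the adjusted p was 0.0865 without the block and 0.00687 with it, and with the block and an estimated correlation it was 0.0608. By edgeR 0 members passed over all genes (0 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom), while in the blocked fit 4 fell adjusted over the list alone. The median was -0.25 within libraries 1 and 2 and -0.23 within libraries 3 and 4. Genes of the unfolded protein response of the endoplasmic reticulum were also lower as a list (median -0.13, camera adjusted p = 2.20e-04, adjusted p = 0.0519 with an estimated correlation). With the block and an estimated correlation the adjusted p was 0.282. Of the 24 tested members 0 passed in either edgeR fit, over all genes or adjusted over the list alone. Calr, a chaperone and the most abundant of them, was at 1839 ± 151 and 1478 ± 220 CPM and did not pass (blocked edgeR adjusted p = 0.489). The list's medians were -0.04 within libraries 1 and 2 and -0.23 within libraries 3 and 4.

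Cell cycle genes were slightly lower as lists, with no single member past the threshold. The S phase list had a median of -0.09 (camera adjusted p = 0.00985, adjusted p = 0.149 with an estimated correlation) and the G2 and M phase list a median of -0.10 (camera adjusted p = 0.00118, adjusted p = 0.0974 with an estimated correlation). Within libraries 1 and 2 the medians were -0.11 for S phase and -0.03 for G2 and M phase, and within libraries 3 and 4 they were -0.10 and -0.22. With the block and an estimated correlation the adjusted p was 0.368 for S phase and 0.3615 for G2 and M phase. In each list 0 of 24 members passed in either edgeR fit, over all genes or adjusted over the list alone. Mcm5 had a log2 fold change of -0.05 and Top2a of -0.07. The S phase call was lost without 4-hydroxytamoxifen 2 (adjusted p = 0.144) or vehicle 3 (0.0601), and the G2 and M phase call without 4-hydroxytamoxifen 3 (0.0619) or 4 (0.0651).

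Cytosolic ribosomal protein genes were higher as a list (median 0.13, 74 of 77 above 0, camera adjusted p = 7.23e-08, adjusted p = 0.460 with an estimated correlation), and so were replication-dependent histone genes (median 0.46, camera adjusted p = 2.29e-04, adjusted p = 0.676 with an estimated correlation). In both lists 0 members passed by edgeR, DESeq2 or limma-voom (3 ribosomal and 2 histone genes at an unadjusted edgeR p under 0.05). Within libraries 1 and 2 the medians were 0.17 for the ribosomal and 0.11 for the histone list, and within libraries 3 and 4 they were 0.11 and 0.72. The histone list, whose transcripts lack poly(A) tails, moved with the libraries rich in 18S RNA. Its summed expression was 140 CPM in 4-hydroxytamoxifen 1 and 205 CPM in 4-hydroxytamoxifen 3, against 105 to 128 CPM in the other 6. Without 4-hydroxytamoxifen 1 and 3 the histone list was lower (adjusted p = 0.00411) and the ribosomal list did not pass (adjusted p = 0.757). Without 4-hydroxytamoxifen 3 alone neither list passed (adjusted p = 0.0619 for the ribosomal and 0.137 for the histone list).

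Some genes listed as markers of cells outside the CD45-positive gate were detected. The most abundant were Mbp and Cnp of the astrocyte and oligodendrocyte list, of whose 23 genes 10 were tested. They were at 143 and 144 CPM with vehicle and 147 and 140 CPM with 4-hydroxytamoxifen. The counts do not tell which cells these transcripts came from, so they do not show that glia were present. Fibroblast, mural and endothelial genes were higher as a list (median 0.26, camera adjusted p = 3.94e-04, adjusted p = 0.151 with an estimated correlation), from a summed 140 ± 44.6 CPM to 184 ± 24.5 CPM. The most abundant of this list were Col1a1, at 44.6 ± 18.996 and 64.2 ± 7.74 CPM, and Sparc, at 39.2 ± 12.7 and 52.8 ± 7.90 CPM. Neither passed the test. The median of this list was 0.19 within libraries 1 and 2 and 0.65 within libraries 3 and 4. Astrocyte and oligodendrocyte genes did not pass (median -0.07, adjusted p = 0.857) and summed to 431 ± 21.3 and 415 ± 28.4 CPM.

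The remaining lists did not pass the threshold. The p53 target genes had a median of 0.07 (adjusted p = 0.354), and in the blocked fit their only member past the threshold was Sesn2 (0.68, adjusted p = 0.0187), which is also on the ATF4 list. Adjusted p-values were 0.564 for microglia-enriched genes, 0.857 for dendritic cell genes, 0.857 for myeloid transcription factors, 0.572 for erythroid and megakaryocyte genes and 0.744 for lymphoid genes. They were 0.989 for ribosome biogenesis, 0.704 for interferon response, 0.546 for inflammatory, 0.342 for immediate early and 0.823 for mitochondrially encoded genes. Spi1 and Irf8, transcription factors of myeloid commitment, had log2 fold changes of -0.08 and -0.01. Over the 26 lists, 13 passed with the preset correlation, 4 with an estimated correlation (ATF4 targets higher, and neutrophil, mast cell and sterol genes lower) and 1 by fry (ATF4 targets).

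**Figure D5:**
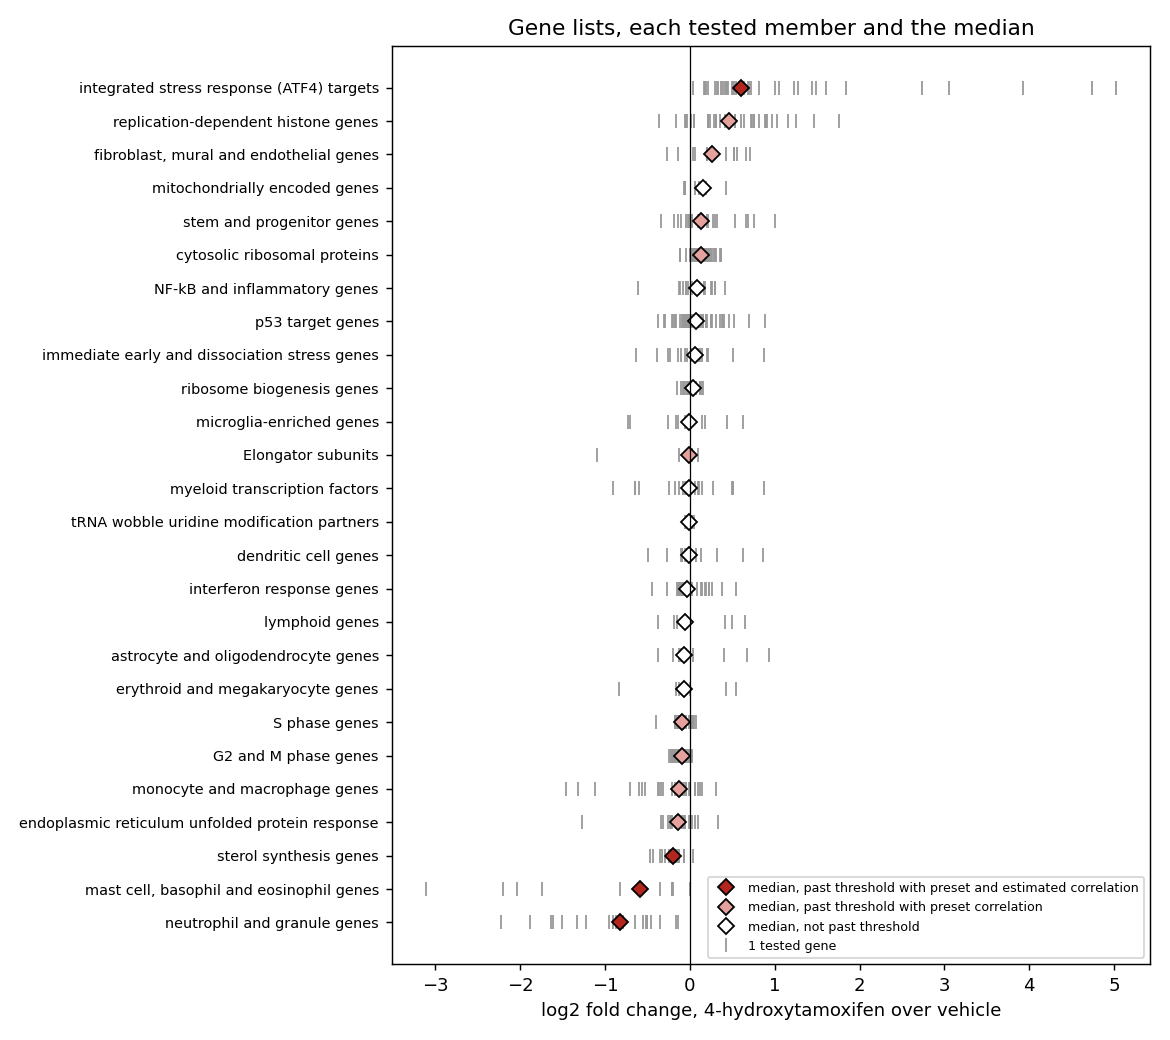
Log2 fold changes of 4-hydroxytamoxifen over vehicle for the 26 tested gene lists, on the x axis, without the block. Each tick is 1 tested gene and each diamond the median of its list, filled dark red where the list passed with both the preset and an estimated correlation, light red where it passed with the preset one only, and white where it did not pass. The ATF4 list has the highest median (0.60) and the neutrophil list the lowest (-0.83).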

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

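The tests of cells carried over, of drug or Cre effects without loss of Elp1, of 18S-rich libraries, of S phase and of early against late granule genes were chosen only after the results were seen. In 248 groups of 4 libraries, 8 had a library far from the other 3, and chance gives about 12.4. Chac1 was at 1.58 CPM in vehicle 2, against 2.66 to 2.85 in the other vehicle libraries. Slc6a9 was at 4.90 CPM in 4-hydroxytamoxifen 2, against 8.80 to 9.14. Dgat2 was at 9.02 CPM in 4-hydroxytamoxifen 3, against 9.96 to 10.1, and Lyz2 at 2396 CPM in the same library, against 3999 to 4151. Irf9 was at 85.2 CPM in vehicle 4, against 53.6 to 56.7. Vehicle 1 stood apart in Prg2, at 7.85 CPM against 2.71 to 3.44, in the summed monocyte and macrophage list, at 11510 CPM against 9236 to 9421, and in the summed myeloid transcription factor list, at 3406 CPM against 3452 to 3461.

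Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least the 9 genes of the real split, so chance cannot be excluded for that count by this test. The other one parted libraries 1 and 2 from 3 and 4 and gave 6963 genes, which points to a structure of the samples. The real split parts all 4 pairs. The other 7 splits that do so gave 0 genes by edgeR without the block, and at most 4 with it, against 41 for the real split. These 8 splits, of which 1 gave 41 or more, are too few for a share under 0.05. For the count of lists, 3 of the 35 splits gave at least the 13 of the real split, and the highest other also gave 13, so chance cannot be excluded there.

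The ATF4 list had the largest median of the 35 splits, 0.598 against 0.576 for the highest other, so 1 split gave as large a value. That count treats all splits alike, although the libraries fall into sets; among the 8 splits that part every pair, too few for a share under 0.05, the blocked median was 0.574 against at most 0.364 in the others. After a fit of fold change on GC content and transcript length, in which 39 of its 40 genes had a value, the list's median residual was 0.613 in the blocked fit, which argues against either as the cause. Astrocyte and oligodendrocyte markers changed by -16.4 CPM and stromal markers by 44.1 CPM, together 27.7 CPM, while the ATF4 list rose by 1606 CPM. Both changes are small beside that rise, but summed marker CPM does not measure cell numbers, so such cells carried over are not excluded. Microglia are CD45-positive, and their list was at 4570 ± 555 CPM with vehicle, with a change of -195. Cst3 alone had a mean of 3206 CPM, so the sum of that list mainly follows 1 gene and cannot exclude microglia. What also stays open is an effect of 4-hydroxytamoxifen or of Cre itself: 0 libraries had the drug with Elp1 kept, so these and the loss of Elp1 cannot be told apart, and either could raise ATF4 targets.

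The fall of neutrophil and granule genes was matched by 3 of the 35 splits, with a highest other median of 0.943 in size against 0.827, so chance is not excluded without the block. Among the splits that part all 4 pairs the real blocked median of -0.85 was the farthest from 0. Leaving out the 18S-rich 4-hydroxytamoxifen 1 and 3 gave a median of -1.04, which argues against those libraries as the cause. Late granule genes changed by -1.17 and early ones by -0.61 on average, with a further fall of the late genes in 3 of 4 pairs (exact two-sided permutation p = 0.371), so a lower share of granulocytes and a change within them may both account for the fall and cannot be told apart. The drug and Cre effects named above stay open here too.

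For the histone list, a median of 0.46 over all libraries became -0.34 without 4-hydroxytamoxifen 1 and 3. For 4-hydroxytamoxifen 3, without which the median was -0.18, a candidate explanation is more RNA without poly(A) tails, as Rn7sk was at 34.0 CPM and Rmrp at 10.4 CPM there. For 4-hydroxytamoxifen 1 the same explanation stays open, with Rn7sk at 3.08 CPM, above the 0.233 and 0.262 CPM of vehicle 1 and 2 but below the 3.68 and 7.33 CPM of vehicle 3 and 4, and Rmrp at 0.0551 CPM, the lowest of the 8. These RNAs did not follow the histone sum in 4-hydroxytamoxifen 2, which had the lowest sum, 105 CPM, with Rn7sk at 6.30 and Rmrp at 2.77 CPM. More cells in S phase would raise S phase genes, whose median over all libraries was -0.088 with an SD of 0.101 over genes. This argues against it for the group, but does not test 4-hydroxytamoxifen 1 and 3 on their own. In these 2 libraries Mcm5 was at 627 and 1123 CPM, against 594 to 1037 CPM with vehicle. Mcm7 was at 422 and 759 CPM, against 433 to 695 CPM, so more S phase stays open for 4-hydroxytamoxifen 3.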

How the results depend on the processing

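With the replicate block the gene count was 41 in place of 9, with all 9 shared. DESeq2 gave 28 and no filter on low counts 14. Leaving out 1 library gave 0 to 10 genes: 0 without vehicle 1 (edgeR, 240 at an unadjusted p under 0.05, 16 by DESeq2, 0 by limma-voom), 0 without 4-hydroxytamoxifen 4 (288, 23 by DESeq2, 0 by limma-voom), 1 without vehicle 2 and 2 without vehicle 4. With 1 library left out, the groups no longer balance the split between libraries 1 and 2 and 3 and 4. That also holds without 4-hydroxytamoxifen 2 or 3, which gave 10 and 8 genes. Whether the imbalance accounts for the lost calls was not tested. Among alternatives chosen after seeing the data, a term for that split gave 30 genes, libraries 3 and 4 alone 100, and the fit without 4-hydroxytamoxifen 1 and 3 gave 0 (edgeR, 318 at an unadjusted p under 0.05, 18 by DESeq2, 0 by limma-voom). The blocked count became 100 with no filter and 21 to 113 without 1 pair, 21 without pair 1 and 113 without pair 2. Elp1 kept its direction in all settings. Its change was -1.10 with RLE factors (adjusted p = 0.0512), -1.19 to -1.003 with 1 library left out (adjusted p = 0.0376 to 0.267) and -1.19 without 4-hydroxytamoxifen 1 and 3 (adjusted p = 0.462), and with the block it passed in all settings run. The list count of 13 was 4 with an estimated correlation, 1 by fry, 7 in libraries 1 and 2 alone, and 8 to 14 with 1 library left out, 8 without 4-hydroxytamoxifen 3. With the block it was again 13, but 1 with an estimated correlation and 2 by fry. In either set of libraries alone no list passed by camera with an estimated correlation. For ATF4 targets that adjusted p was 0.279 in libraries 1 and 2 and 0.144 in libraries 3 and 4. For neutrophil genes it was 0.814 and 0.384. The adjusted p-values of lists that follow are from camera with the preset correlation. In adjusted p, libraries 1 and 2 alone lost the lists of the unfolded protein response (0.365), stem (0.516), monocyte (0.693), fibroblast (0.457), G2 and M phase (0.454) and histone genes (0.454), and libraries 3 and 4 alone lost Elongator (0.230) and S phase (0.0897) and gained immediate early genes (0.0264). Without 4-hydroxytamoxifen 1 and 3 the histone list reversed (0.00411), the ribosomal list also changed direction (0.757), stem (0.580) and monocyte genes (0.412) were lost and mitochondrial genes passed (0.0447). Limma-voom lost Elongator (0.0685). With 1 library left out the adjusted p ranged from 0.00163 to 0.157 for Elongator, 5.90e-06 to 0.205 for stem, 2.94e-13 to 0.137 for monocyte, 0.0158 to 0.996 for microglia-enriched, 0.00662 to 0.144 for S phase, 2.42e-04 to 0.0651 for G2 and M phase, 1.62e-12 to 0.0619 for ribosomal, 0.0194 to 0.948 for immediate early and 2.32e-08 to 0.137 for histone genes, the last reversed without 4-hydroxytamoxifen 3. Microglia-enriched genes passed without vehicle 2, and immediate early genes without 4-hydroxytamoxifen 2. Except where fewer samples or genes explain it, the cause was not tested. Of 1817 values for single genes other than Elp1 under alternatives, 1670 kept their side of the threshold, 103 newly passed and 44 were lost. Only the 8 rises that passed in the main fit could be lost, so the 44 losses all fell on them. The total of 1817 therefore does not measure how stable the calls were. For the lists, 462 of 494 values kept their side, 4 newly passed, 25 were lost and 3 reversed. Direction was compared only where at least 1 of the 2 values passed. The block changed no list call with the preset correlation. Low depth limits Slc7a3, Aldh1l2 and Cth, with 3, 11 and 14 vehicle reads.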

Other observations

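Beyond the genes that passed, members of the ATF4 list for transfer RNA charging and serine synthesis had values above 0, and these genes were picked after the values were seen. In the blocked fit the cysteinyl-tRNA synthetase gene Cars rose by 0.59 (edgeR adjusted p = 0.0126), while Gars (0.38), Aars (0.40), Yars (0.36), Sars (0.31) and Wars (0.03) did not pass. The serine synthesis genes Psat1 (0.44), Psph (0.56) and Phgdh (0.42) and the arginine transporter Slc7a1 (0.48, adjusted p = 0.0508) did not pass either.

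Some genes outside the ATF4 list also passed in the blocked fit and were picked in the same way. Xist, the RNA that coats the inactive X chromosome, rose by 0.51 (adjusted p = 0.0306) in 4 of 4 pairs, from 244 ± 64.5 to 348 ± 93.3 CPM, and did not pass by edgeR over the 8 libraries without the block. Neat1, another nuclear RNA, had a blocked log2 fold change of 0.33 and did not pass (adjusted p = 0.7497). The ion channel gene P2rx3 rose by 2.40 (adjusted p = 0.0214) from 29 to 137 reads, and Aqp9, a channel for water and glycerol, rose by 0.87 (adjusted p = 0.0187).

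A hypothesis written before its test was that transcripts rich in AAA, GAA and CAA codons, which are read by transfer RNAs that Elongator modifies, may be lower after Elp1 loss. Across 11446 genes the Spearman correlation of the log2 fold change with the share of these codons was 0.0505, and given GC content at the third codon position it was -0.0176, above the limit of -0.05 set for a negative result. Genes are not independent replicates, and 34 of 70 signed splits of the libraries gave a value as low. In the fit with the replicate block the value was -0.0236, and the SD of the blocked value over the other splits that part all pairs was 0.121, so it lies within its spread and the test leaves the hypothesis open. That comparison with the spread was added after the value was seen. These data measure transcript levels, and translation was not tested.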
